A study of Rattus norvegicus with 8 samples.

How the data were processed

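Gene expression was measured in NR8383 cells, a macrophage line established from rat lung lavage, after 4 h with ZnO at 4 µg/mL or at 16 µg/mL. There were 4 arrays per dose, described in the series' design as biological replicates, and each array had its own file. Replicates are named by dose and by the number in the sample titles. Untreated cells, which the series' design also mentions, were not analysed here, so the only comparison was ZnO 16 minus ZnO 4.

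Per the labels' protocols, cRNA labelled with Cy3 was hybridised to 1-colour Agilent arrays. The deposited files are scanner output from Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. They hold the processed signal, a linear intensity that Feature Extraction had background-subtracted and detrended within each array per the file headers, beside raw median intensities of the spot and of its local background. No normalization between arrays had been applied to the deposited intensity values. The other deposited columns used are 0 or 1 flags for spots well above background, saturated, non-uniform or outlying among repeated spots.

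Each array had 62976 spots, and 45598 distinct probes remained after control spots were left out. The files give accessions rather than gene names. Accessions were matched without versions to a RefSeq gene table of assembly GRCr8, which was used for names only, since the file headers name another build. A symbol was found for 21109 probes (46.3%), and 24489 kept their accession. Among curated mRNA accessions (NM) 93.9% matched, and none of the 6958 ENSRNOT accessions did.

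The log2 of the processed signal minus each array's 75th percentile over non-control spots was used throughout. Spots with a non-uniformity or population outlier flag were set to missing, spots of a probe were averaged, and a probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 dose. The probe with the highest mean over the 8 arrays stood for its gene. This left 13464 features, called genes below, of which 7980 had a symbol. No spot had a saturation flag. Signal over background limits what can be measured: 188 genes were not well above background on any array at 4 µg/mL and 475 on none at 16 µg/mL. For such a gene the fold is given as "at least N-fold". This was done where the probe was not well above background on any array of the dimmer dose. It sets the mean of the brighter dose against the mean, at the other dose, of the higher of each array's lowest well-above-background signal and the probe's own value. The bound holds for this processing and was not kept in every setting run. The number of arrays limits the precision of every difference.

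Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated data, with the spread of the 13304 genes that had no missing value and 200 genes changed, 6% of changes of 0.5 on the log2 scale were recovered, 62% of changes of 1, 92% of changes of 2 and 98% of changes of 3, and 6 unchanged genes were called. With more genes changed the adjustment is less strict, and 5614 of 13464 genes were called in the data. These shares therefore do not give the recovery for this comparison. Each of 36 gene lists was fixed before the data were examined. Lists with at least 3 measured members (35 of them) were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. In the simulation, raising the heat shock list by 1 led camera to call that list and 0 others. The simulated genes varied independently of each other, so this does not test camera where members of a list vary together. Array-level measures were compared with a two-sided exact permutation test over 70 assignments.

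The genes named were set by a rule, also fixed before the data were examined. It takes the 8 largest fitted rises and the 8 largest fitted falls, ordered without regard to background, among called genes whose doses did not overlap, that were well above background on all 4 arrays of the higher dose and that had an ordinary symbol. It adds 9 textbook readouts of zinc and stress (Mt1, Mt2A, Slc30a1, Hmox1, Hspa1b, Ddit3, Atf3, Il1b and Tnf), of which Hspa1b was not among the tested genes. For each list called by camera, or with at least 1/3 of its measured members called, it takes the 3 largest differences in the majority direction and the largest in the other. For other lists it takes at most 2 called members. This gave 119 genes, of which 3 are not described.

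Each dose lay on a slide of its own, scanned separately, and the sample descriptions give 20 passages for the ZnO 4 cultures and 200 for the ZnO 16 cultures. Whether these passage numbers are right, or a slip in the labels, cannot be told from the data. Dose, slide, scan and passage number cannot be told apart in these data. A low-signal area was found on 2 arrays by comparing tiles of 8 rows by 8 columns with the other arrays of the dose, a check chosen after the data had been seen. It covered 2616 spots (4.46%) of ZnO 4 replicate 4 and 596 spots (1.02%) of ZnO 16 replicate 4. Genes whose probe lay in it are also given with those spots set to missing.

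Alternatives planned before the data were examined covered other normalizations, filters, probe rules, variance models, the replicate number as a block, a minimum fold, other list tests and leaving out each array in turn. The planned normexp background correction needs mean spot intensities, and the files hold only median ones, so it was run on the median signals. That setting, the masked low areas and the removal of both arrays numbered 4 were chosen after the data had been seen. In settings that shifted all genes, a gene's difference is given relative to the median of all genes. The adjusted p printed beside it tests the difference before that median was taken off.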

Results

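Gene expression in NR8383 rat alveolar macrophages was compared between 4 arrays of cells exposed to 16 µg/mL ZnO and 4 arrays of cells exposed to 4 µg/mL ZnO, both for 4 h. The comparison asks which transcripts differed between the higher and the lower dose. Between 31.4% and 39.3% of probes were well above background on an array. Correlations across genes were 0.973 to 0.991 between arrays of the lower dose, 0.9695 to 0.9863 between arrays of the higher dose and 0.9145 to 0.9474 between doses; genes are not independent replicates. Differences below are ZnO 16 minus ZnO 4 on the log2 scale, and levels are log2 signals relative to each array's 75th percentile, with SD and n = 4.

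Among called genes with an ordinary symbol whose doses did not overlap, the largest fitted rises at 16 µg/mL included immediate early genes and stress genes. This order counts signals below background. By their bounds Fos and Egr1, below, rank under Chac1 and Ddit4, and among the falls Caprin1 and Alkbh4 rank under Myc. With the low-signal area masked, Ddit3 and Ppp1r10, below, also rank under Chac1 and Ddit4. Dusp1, a phosphatase that inactivates MAP kinases, stood at 1.40 ± 0.35 at 16 µg/mL and was not well above background at 4 µg/mL, at least 51.6-fold higher (adjusted p = 7.51e-08). Under the same limit, the inducible chaperone Hspa1a was at least 41.5-fold higher, the secreted peptide gene Gpr15lg at least 45.7-fold, and the transcription factors Fos and Egr1 at least 21.5-fold and 8.97-fold. In some settings run, the differences of all these genes were smaller than their bounds. Atf3, a stress-induced transcription factor, rose from -0.25 ± 0.26 to 4.54 ± 0.09, a difference of 4.79 (SE 0.14, adjusted p = 3.18e-08). Ddit3, which encodes CHOP, rose by 4.82 (SE 0.82) and Ppp1r10, a regulatory subunit of a protein phosphatase, by 4.89 (SE 1.20). The Ddit3 and Ppp1r10 probes lay in the low-signal area of ZnO 4 replicate 4: with that area masked the differences were 3.94 for Ddit3 and 3.58 for Ppp1r10, and without that array 3.78 and 3.34. Without ZnO 4 replicate 1 the Ppp1r10 difference was 5.56. The Gpr15lg probe also lay in this area, and its call was kept with the area masked. The 3 Ppp1r10 probes ranged from 1.91 to 4.89. The second Hspa1a probe was at least 2.30-fold higher. The high sequence identity of Hspa1a and Hspa1b leaves the source of the Hspa1a signal uncertain.

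Among the largest fitted falls were those of Aldh1l2, a mitochondrial folate enzyme, which was at least 18.1-fold lower at 16 µg/mL (adjusted p = 1.70e-07), and of Grm6, a glutamate receptor gene, at least 10.3-fold lower. Under the same limit Banf1, a chromatin-binding protein of the nuclear envelope, was at least 7.70-fold lower, Caprin1, an RNA-binding protein of stress granules, at least 4.87-fold and Alkbh4 at least 3.43-fold; the Alkbh4 call was lost with normexp (-0.73 relative to all genes, adjusted p = 0.0751). Tnfaip2, a TNF-induced gene, and Id1, an inhibitor of helix-loop-helix transcription factors, were each well above background on 1 of 4 arrays at 16 µg/mL. With signals below each array's lowest well-above-background signal raised to it, their differences were -4.43 (adjusted p = 1.84e-05 as fitted) and -3.42 (adjusted p = 3.28e-06 as fitted).

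**Figure D1:**
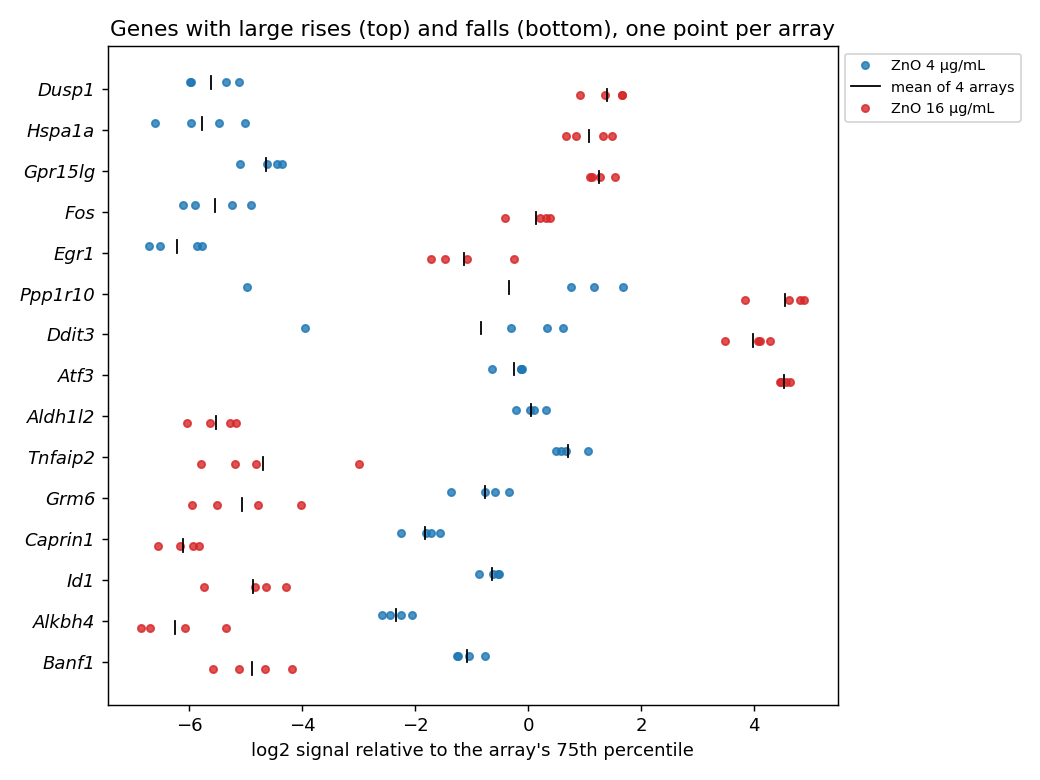
Log2 signal relative to the 75th percentile of the array (horizontal axis) for the 8 genes with the largest fitted rises and 7 of the 8 with the largest fitted falls under the naming rule, signals below background included; each point is an array, and short vertical lines mark the mean of the 4 arrays of a dose. The doses do not overlap for any of these genes, which the rule required, and ZnO 4 replicate 4 lies far below the other arrays for Ppp1r10 (-4.98 against a mean of 1.202 on the others of its dose).

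Of 13464 genes, 5614 (41.7%) passed the threshold, 2672 higher and 2942 lower at 16 µg/mL. Of these, 2510 differed by at least 1 on the log2 scale, 924 higher and 1586 lower. The 4 values of 1 dose lay wholly beyond those of the other for 39.9% of genes, where chance gives 2.86%. Among genes with a symbol 23.5% were higher and 16.8% lower, and among those without one 14.5% were higher and 29.2% lower. The split between higher and lower depended on the filter and on the scaling. Of the calls, 377 lower ones were in genes not well above background on any array at 16 µg/mL. Those not well above background on any array at 4 µg/mL gave 152 higher calls. With signal well above background required on all arrays, 2271 genes were higher and 2125 lower. The median gene differed by 0.01 after 75th percentile scaling, by 0.17 after median scaling, by -0.75 without scaling and by -0.76 after scaling to the spike-ins. The calls were then 3408 higher and 1979 lower with median scaling, 230 higher and 4412 lower without scaling and 227 higher and 4653 lower with spike-in scaling. With normexp on the median signals the median gene differed by 0.15, with 2781 higher and 1996 lower. Gene differences given with normexp relative to all genes have this 0.15 taken off, while the adjusted p beside them tests the difference before that. Every difference below is relative to the 75th percentile of the array.

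Among genes of zinc handling 1 metallothionein was lower, and 1 exporter and 3 importers were higher. Mt1, a metallothionein that binds zinc, fell by 0.61 (SE 0.17, adjusted p = 0.0159), and the difference for Mt2A was -0.10 (SE 0.14, adjusted p = 0.566). Both were bright at each dose, Mt1 at 7.19 ± 0.27 and 6.59 ± 0.21 and Mt2A at 3.16 ± 0.21 and 3.05 ± 0.15 at 4 and 16 µg/mL. They were the only 2 measured members of the metallothionein list, which was too short for camera; 1 was called lower, and likewise adjusted over the list alone. With both arrays numbered 4 left out the Mt1 difference was -0.43 (adjusted p = 0.0657). Spike-in probes near the brightness of Mt1 also differed between the slides, and in both directions. One stood at 7.036 on the ZnO 4 slide and 6.35 on the ZnO 16 slide (-0.69), another at 6.134 and 7.236 (1.102). The Mt1 fall was no larger than these differences, so it cannot be told from a difference between slides. The same limit holds for any other gene difference or list median no larger than these. Of 5 measured SLC30 zinc exporters, 1 was called higher and 0 adjusted over the list alone (camera adjusted p = 0.524). It was the plasma membrane exporter Slc30a1, which differed by 0.35 (SE 0.12, adjusted p = 0.0331). That call was lost on leaving out any array other than ZnO 16 replicate 3 (differences of 0.32 to 0.37, adjusted p of 0.0566 to 0.0794). Of 10 SLC39 importers, 3 were called higher, also adjusted over the list alone (camera adjusted p = 0.319; fry, which does not compare the list with other genes, adjusted p = 0.0455). They included Slc39a7 (0.76) and Slc39a4 (0.61), and the latter call was lost without ZnO 4 replicate 2 or without ZnO 16 replicate 2 or 3 (0.48 to 0.58, adjusted p of 0.0501 to 0.0521). The calls of Slc30a1 (0.16 relative to all genes, adjusted p = 0.0787) and Slc39a4 (0.15, adjusted p = 0.121) were lost with normexp.

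Camera called lists of protein stress genes higher. In the heat shock list 13 of 19 measured members were higher and 1 lower (14 and 1 adjusted over the list alone), with a median difference of 0.84 and a camera adjusted p of 5.09e-06, or adjusted p = 0.0752 with an estimated correlation. Besides Hspa1a, the co-chaperone Bag3 rose by 2.96 (SE 0.16; 2.80 with the low area masked) and the Hsp110 gene Hsph1 by 2.73 (SE 0.20). The constitutive Hsp90ab1 differed by -0.43, a call lost without ZnO 4 replicate 2, 3 or 4 or ZnO 16 replicate 3 (-0.43 to -0.36, adjusted p of 0.0540 to 0.0772). In the ATF4 and CHOP list, which holds targets of the integrated stress response, 15 of 20 were higher and 0 lower, also adjusted over the list alone, with a median of 1.58 and a camera adjusted p of 5.24e-09, or adjusted p = 0.181 with an estimated correlation. After Ddit3 and Atf3 its largest fitted rise was in Chac1, a glutathione-degrading enzyme (4.47, SE 0.28). With the low area masked Ddit3 (3.94) ranked under Chac1. The call of Hsp90ab1 (-0.50 relative to all genes, adjusted p = 0.0778) was lost with normexp.

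Among tRNA synthetases 7 of 20 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0775), with Cars1 at 1.91 (1.47 with the low area masked), Sars1 at 1.35, Yars1 at 0.91 and Nars1 at -1.52. The camera call was made without ZnO 4 replicate 3 (adjusted p = 0.0434), ZnO 16 replicate 2 (0.0372) or ZnO 16 replicate 3 (0.0388), where the list median was 0.22, 0.28 and 0.28 above that of all genes. In the list of ER chaperones and ER-associated degradation 7 of 22 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.222). Dnajb9 rose by 1.97 (SE 0.29), Herpud1 rose by 1.05 (SE 0.16) and Sec61b, a translocon subunit, fell by 1.63. Syvn1 differed by 0.84 and by 0.58 (adjusted p = 0.0828) with the low area masked; its call was kept only without ZnO 4 replicate 2 or ZnO 16 replicate 4 among the 8 arrays left out in turn, with differences of 0.58 to 0.95 (adjusted p of 0.0520 to 0.115) in the others. The call of Nars1 (-0.40 relative to all genes, adjusted p = 0.454) was lost with normexp.

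Oxidative stress genes went both ways. In the NRF2 list 5 of 23 were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.300). Osgin1, an oxidative stress response gene, rose by 4.06 (SE 0.28), Hmox1, the heme-degrading oxygenase, rose from 5.21 ± 0.32 to 7.33 ± 0.28 (4.35-fold, adjusted p = 1.99e-05) and Srxn1, sulfiredoxin, rose by 1.40. The ferritin heavy chain Fth1 fell by 1.96 (SE 0.40). In the iron and ferroptosis list 5 of 15 were higher and 1 lower (camera adjusted p = 0.163; 5 and 1 adjusted over the list alone), among them Hmox1, the iron transporter Slc11a1 (0.98) and the ferrireductase Steap3 (0.998). The call of Steap3 was lost without ZnO 4 replicate 2 or 3 or ZnO 16 replicate 3 (0.85 to 0.92, adjusted p of 0.0504 to 0.0561). The call of Slc11a1 (0.37 relative to all genes, adjusted p = 0.0559) was lost with normexp.

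Immediate early genes had the highest median difference of the 36 lists. Of 24 measured members 20 were higher and 1 lower, also adjusted over the list alone, with a median of 2.10 and a camera adjusted p of 1.70e-10, or adjusted p = 0.147 with an estimated correlation. Dusp1, Fos and Egr1, described above, led it. Egr2 fell by 0.70 on its brighter probe, while its other probe differed by -0.02. Of the NF-kB feedback genes 8 of 15 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0557, and 0.0414 with the low areas masked or 0.0434 without ZnO 4 replicate 3, where the list median was 0.60 above that of all genes). The inhibitor Nfkbib rose by 1.47 (SE 0.12), the ribonuclease Zc3h12a by 1.44 (SE 0.22) and the adhesion molecule Icam1 by 1.35 (SE 0.12), and the inhibitor Nfkbia fell by 0.72 (SE 0.17). The call of Egr2 (-0.23 relative to all genes, adjusted p = 0.726) was lost with normexp.

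Secreted inflammatory mediators went both ways. Il1b fell by 1.82 (SE 0.22, adjusted p = 0.000121) and Tnf by 1.23 (SE 0.22, adjusted p = 0.00171); the second Tnf probe, not well above background at 16 µg/mL, did not pass (adjusted p = 0.236). In the cytokine and chemokine list 5 of 14 were higher and 6 lower (5 and 7 adjusted over the list alone; camera adjusted p = 0.675). The chemokine Ccl22 differed by -2.25 (-2.29 with the low area masked) and its second probe by -0.27, Cxcl10 fell by 2.16 (SE 0.27), and the growth factor gene Csf3 was at least 3.27-fold lower, a call lost with normexp (-0.63 relative to all genes, adjusted p = 0.1504). Oncostatin M (Osm) was at least 19.5-fold higher. Of the inflammasome list 0 of 8 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.310): Il1b, and Txnip, a thioredoxin-binding protein, at least 4.54-fold lower and well above background on 3 of 4 arrays at 4 µg/mL. Interferon response genes had 3 of 23 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.984), with the peptide transporter Tap1 at 0.95 and Mx1 at -0.87; the median (-0.02) and the mean (-0.03) of this list were negative while the camera direction was up. The call of Mx1 (-0.31 relative to all genes, adjusted p = 0.421) was lost with normexp.

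Phagocytic receptor genes had 1 of 16 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.218). Tlr4, the receptor for bacterial lipopolysaccharide, fell by 1.92 (SE 0.21), Tlr2 by 1.38 (SE 0.14) and the scavenger receptor Olr1 by 1.36 (SE 0.29). Fcgr3a differed by 0.40, a call lost without ZnO 4 replicate 1, 3 or 4 or ZnO 16 replicate 2 or 3 (0.32 to 0.40, adjusted p of 0.0542 to 0.0874). Of the macrophage identity genes 2 of 19 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.852), with the endosomal glycoprotein Cd68 at -1.74 and Csf2ra at 0.98. In the antigen presentation list 2 of 6 were higher and 1 lower (camera adjusted p = 0.649; 2 and 1 adjusted over the list alone). RT1-DMa differed by 0.75, RT1-Db1 by -0.83 and RT1-DMb by 0.77, and the RT1-DMb call was lost without ZnO 4 replicate 3 (0.63, adjusted p = 0.0505). The calls of Fcgr3a (-0.29 relative to all genes, adjusted p = 0.431) and RT1-Db1 (-0.18, adjusted p = 0.933) were lost with normexp.

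**Figure D2:**
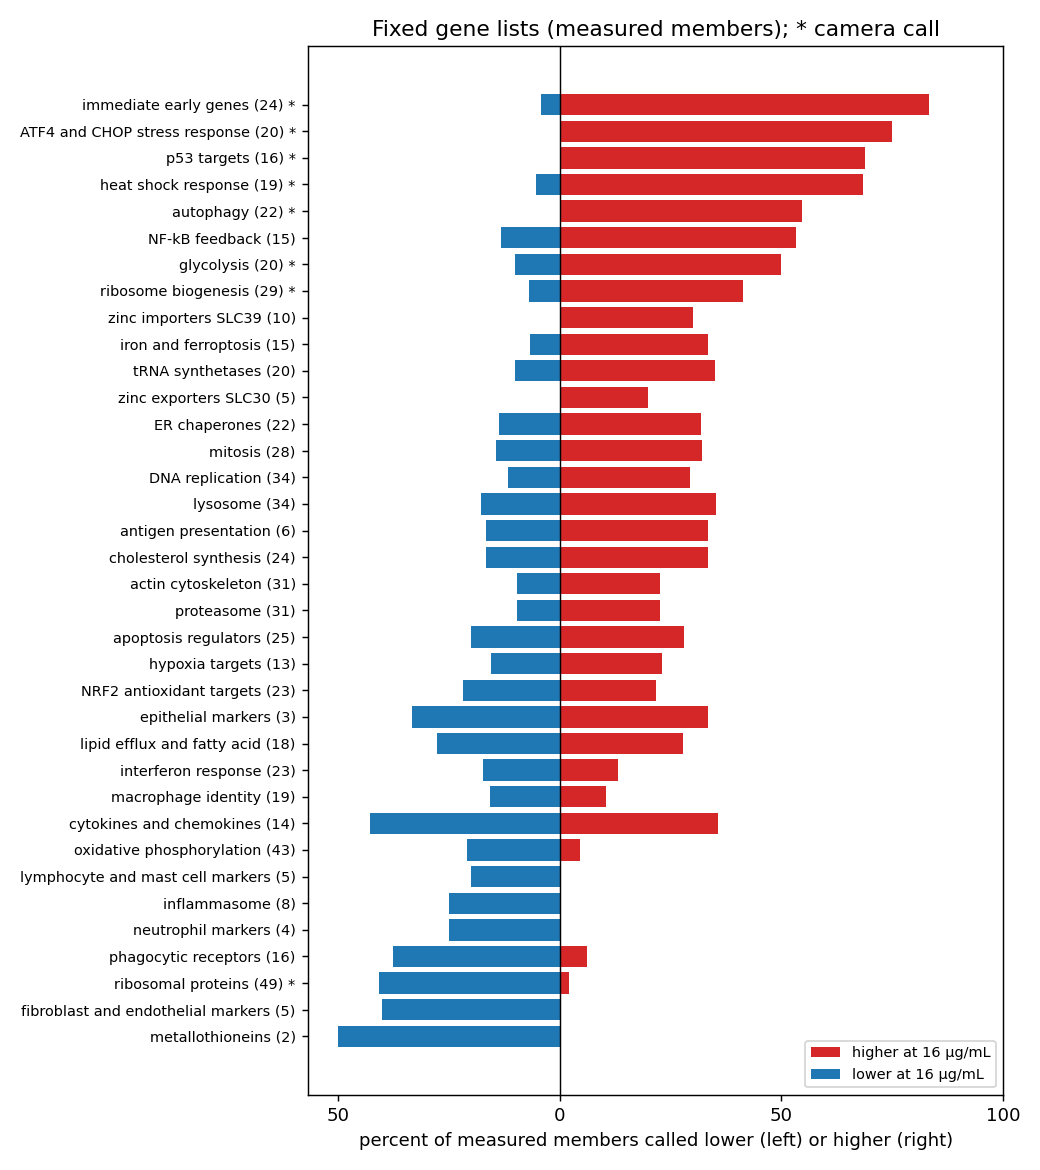
Percent of the measured members of each fixed list that passed adjusted p under 0.05, higher at 16 µg/mL to the right and lower to the left, with the number of measured members in brackets and an asterisk where camera called the list at the preset correlation. Immediate early genes (20 of 24 higher) and ATF4 and CHOP targets (15 of 20) lie at the top, and ribosomal proteins (20 of 49 lower) near the bottom.

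Of the targets of p53, a transcription factor of the DNA damage response, 11 of 16 members were higher and 0 lower, also adjusted over the list alone, with a median of 0.58 and a camera adjusted p of 0.00272, or adjusted p = 0.145 with an estimated correlation. Gadd45a, a DNA damage and stress gene, rose by 3.15 (SE 0.18), the kinase gene Plk3 by 2.83 (SE 0.22) and the cyclin-dependent kinase inhibitor Cdkn1a by 1.96 (SE 0.19). Apoptosis regulators went both ways, with 7 of 25 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.382). The anti-apoptotic Bcl2l1 was at least 2.33-fold higher on a probe not well above background at 4 µg/mL, the pro-apoptotic Bak1 rose by 0.83, and the caspase gene Casp12 was at least 1.31-fold higher, a call lost without any 1 of the 4 arrays at 4 µg/mL (differences of 0.83 to 0.85, adjusted p of 0.0646 to 0.0693). The 2 probes of Xiap, an inhibitor of caspases, disagreed, the brighter at -1.18 and the other, not well above background at 4 µg/mL, at least 1.34-fold higher, both past the threshold. The calls of Casp12 (0.43 relative to all genes, adjusted p = 0.0587) and Xiap (-0.43, adjusted p = 0.361) were lost with normexp.

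Autophagy genes had 12 of 22 higher and 0 lower (12 and 1 adjusted over the list alone), with a median of 0.60 and a camera adjusted p of 0.00512, or adjusted p = 0.181 with an estimated correlation and 0.160 with normexp on the median signals, where the median was 0.25 above that of all genes. Wipi2 rose by 1.45 (SE 0.12), Atg14 by 1.26 (SE 0.13) and Gabarapl1 by 1.20 (SE 0.11; also 1.20 with the low area masked); all are genes of autophagosome formation. Lysosomal genes had 12 of 34 higher and 6 lower (13 and 7 adjusted over the list alone; camera adjusted p = 0.293), with the hydrolase Glb1 at 1.51 (0.78 with the low area masked), the proteases Ctsl at 1.07 and Ctsz at 0.98, and Cd68 as the largest fall. Proteasome genes had 7 of 31 higher and 3 lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.293), with Psmd12 at 1.13 (0.71 with the low area masked) and Psma2 at -0.81. The call of Ctsz (0.15 relative to all genes, adjusted p = 0.115) was lost with normexp.

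Ribosomal protein genes were the 1 list that camera called lower: 20 of 49 members were lower and 1 higher, also adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.00492, or adjusted p = 0.686 with an estimated correlation, which was 0.49 for this list). Rplp1 fell by 1.66 (SE 0.22), Rps23 by 1.40 (SE 0.21) and Rpl19 by 1.23 (SE 0.19). The probes of Rps29 ranged from -0.93 to 0.42; the brightest was called higher and the other 2 lower, and the higher call was lost without any 1 of replicates 1, 2 or 3 of either dose (0.34 to 0.46, adjusted p of 0.0573 to 0.123). Many near-identical copies of ribosomal protein genes make their probes' targets uncertain. Genes of ribosome biogenesis had 12 of 29 higher and 2 lower, also adjusted over the list alone, with a median of 0.29 and a camera adjusted p of 0.0260, or adjusted p = 0.181 with an estimated correlation. The nucleolar factors Bop1, Gnl3 and Bysl rose by 1.43, 1.34 and 1.30, and Myc, a transcription factor that drives ribosome production, fell by 2.51 (SE 0.14). The list's call was lost without ZnO 4 replicate 1 (adjusted p = 0.0512), ZnO 4 replicate 4 (0.0818) or ZnO 16 replicate 1 (0.0594), where its median lay 0.19 to 0.27 above that of all genes, and with median scaling (0.0575), no scaling (0.146) and spike-in scaling (0.130), where that median stayed at 0.29. It was also lost with both arrays numbered 4 left out (0.154; median 0.16) and with normexp (0.319; median 0.03). The call of Rps29 (-0.29 relative to all genes, adjusted p = 0.462) was lost with normexp.

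Among genes of energy metabolism, glycolysis had 10 of 20 higher and 2 lower (12 and 2 adjusted over the list alone), with a median of 0.52 and a camera adjusted p of 0.0138. That call was lost with an estimated correlation (adjusted p = 0.587), with no scaling (0.129) and spike-in scaling (0.118), where the median relative to all genes stayed at 0.51, and with normexp (0.160), where it was 0.23. The glucose transporter Slc2a1 rose by 1.42 (SE 0.15), Pfkfb3, which makes an activator of glycolysis, by 1.29 (SE 0.12) and the phosphofructokinase Pfkl by 1.02 (SE 0.19), and the kinase Pdk1 fell by 0.88. Genes of oxidative phosphorylation had 2 of 43 higher and 9 lower (1 and 8 adjusted over the list alone; camera adjusted p = 0.293, and 0.00824 with normexp, where the list was lower), with Cox7c at -2.22 once signals were raised in the same way, since it was well above background on 1 of 4 arrays at 16 µg/mL. Among hypoxia targets 3 of 13 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.534). Ddit4, an inhibitor of mTOR signalling, rose by 4.45 (SE 0.13, adjusted p = 3.18e-08), Adm, the adrenomedullin gene, by 1.39 and Ndrg1 by 0.60, and Ankrd37 fell by 0.99; the Ndrg1 difference was -0.01 with normexp once the shift of all genes was taken off. The call of Ankrd37 (-0.39 relative to all genes, adjusted p = 0.315) was lost with normexp.

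Cholesterol synthesis genes had 8 of 24 higher and 4 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.411), with Nsdhl and Dhcr7 both at 0.78 and the squalene synthase Fdft1 at -1.70. With normexp the calls of Nsdhl (0.05 relative to all genes, adjusted p = 0.199) and Dhcr7 (0.07, adjusted p = 0.258) were lost. In the list of lipid efflux and fatty acid genes 5 of 18 were higher and 5 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.792). Mylip, a ubiquitin ligase, rose by 1.21, the sterol receptor Nr1h2 by 1.20 (1.15 with the low area masked) and the lipid droplet gene Plin2 by 0.70. The 2 probes of Srebf1 disagreed at -1.45 and 0.82, both past the threshold.

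Cell cycle and cytoskeletal lists went both ways. Mitosis genes had 9 of 28 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.293), with Prc1 at 1.67 (1.40 with the low area masked; its second probe 0.11), Ndc80 at 1.53 (1.31 masked), the phosphatase Cdc25b at 0.80 and the kinase Plk1 at -0.92. DNA replication genes had 10 of 34 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.293). Rfc2 rose by 0.66, the primase subunit Prim2 fell by 1.52, and the licensing factor Cdt1 (0.99) and the polymerase Pold1 (0.88) differed with overlapping doses; both calls were lost without ZnO 4 replicate 1 or 3 or ZnO 16 replicate 3 (0.82 to 0.94 for Cdt1, 0.74 to 0.85 for Pold1, adjusted p of 0.0509 to 0.0580). In the actin cytoskeleton list 7 of 31 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.293), with gelsolin (Gsn) at 2.38 and Actn1 at 2.03, or 1.71 and 1.45 with the low area masked; without ZnO 4 replicate 4 the Gsn difference was 1.71 too. The call of Cdc25b (0.25 relative to all genes, adjusted p = 0.0771) was lost with normexp.

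Few markers of other cell types were measured. For neutrophils 1 of 4 was lower, also adjusted over the list alone (camera adjusted p = 0.792), which was Camp (-0.84). For epithelial cells 1 of 3 was higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.984). These were Napsa at 0.51, lost without ZnO 4 replicate 1, 2 or 3 or ZnO 16 replicate 2 or 3 (0.41 to 0.55, adjusted p of 0.0562 to 0.102), and Foxj1, whose probes disagreed, the brighter at -1.87 and the other, not well above background at 4 µg/mL, at least 6.51-fold higher. For fibroblasts and endothelium 2 of 5 were lower, also adjusted over the list alone (camera adjusted p = 0.293), with Pecam1 at -1.08 and Vwf at -0.95 on its brighter probe and 0.89 on the other. For lymphocytes and mast cells 1 of 5 was lower, also adjusted over the list alone (camera adjusted p = 0.630): Cd3d was at least 1.71-fold lower, a call lost with normexp (-0.13 relative to all genes, adjusted p = 0.934). The median, mean and camera direction differed in sign for the neutrophil list (0.10, 0.09 and down) and the epithelial list (0.51, -0.27 and up). The call of Napsa (-0.23 relative to all genes, adjusted p = 0.735) was lost with normexp.

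Of the 35 lists tested, camera called 7 higher and 1 lower at the preset correlation, 0 were called with an estimated correlation (6 had an unadjusted p under 0.05), and fry, which asks whether a list's genes move on balance one way, called 23. A higher correlation does not explain every lost call. The estimate was 0.0080 for heat shock, -0.021 for p53 targets and 0.0084 for ribosome biogenesis, under the preset 0.01. For p53 targets the unadjusted camera p still rose from 0.00031 to 0.0083. The estimate was 0.022 to 0.486 for the other called lists. With 41.7% of all genes past the threshold, a list with a similar share of called members does not stand apart from the rest. Camera compared each list, whose members have symbols, with all other measured genes, including those without one. Without a symbol, median differences were -0.22 for ENSRNOT and -0.12 for other accessions. With one, they were 0.09 for NM and -0.11 for other accessions. This background favours calls of higher, and camera among genes with a symbol alone was not run.

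No array-level measure passed after adjustment, but with 4 measures a single one at the smallest possible exact p could not pass. The spike-in slopes did not overlap, at 0.806 to 0.869 on the ZnO 16 slide and 0.987 to 1.014 on the ZnO 4 slide. The slope of measured against nominal spike-in amount was 0.846 ± 0.028 (SD, n = 4) on the ZnO 16 slide and 0.999 ± 0.012 (SD, n = 4) on the ZnO 4 slide (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow; adjusted p = 0.114 over 4 measures). The 75th percentile of the processed intensity was 274 ± 121 at 16 µg/mL and 434 ± 88.5 at 4 µg/mL (exact permutation p = 0.114, adjusted 0.229), the share of probes well above background 33.4% ± 1.94 and 35.3% ± 3.06 (exact permutation p = 0.343, adjusted 0.457) and the median CV of repeated probes 7.77% ± 1.37 and 8.57% ± 6.16 (exact permutation p = 1, adjusted 1). Relative to the 75th percentile, 5 of the 7 spike-in probes well above background on all arrays were brighter on the ZnO 16 slide, by 1.102 to 1.603 on the log2 scale, and 2 were dimmer, by -0.21 and -0.69. No slide held both doses. Gene differences and list medians no larger than these spike-in differences cannot be told from a difference between slides. This covers, among others, the medians of the heat shock list (0.84) and of the ribosomal protein list (-0.36). Larger differences still cannot be assigned to the dose rather than to the slide.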

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

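Groups of 4 arrays were screened for an array standing apart, for the named genes and 6 array-level measures: 235 groups were examined and 17 had a gap to the nearest other array that exceeded the 95% critical value of Dixon's test, where chance at 1 in 20 gives 11.8. Gaps are given as a share of the range of the 4 arrays. The tests of the low-signal area, of genes without a symbol, of probe pairs and of slides were chosen only after the results were seen, and the count over splits of the samples was planned.

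ZnO 4 replicate 4 was the array apart in 7 of the 17. Its level was low for Ppp1r10 (gap 0.862 of the range; -4.98 against a mean of 1.202 on the other arrays), Gsn (0.868; -0.48 against 2.23), Actn1 (0.899; -3.39 against -1.05), Glb1 (0.847; -1.65 against 0.45) and Psmd12 (0.915; 1.245 against 2.908), whose probes lay in the low-signal area, and for Atf3 (0.959; -0.64 against -0.12), whose probe did not. Its median CV of repeated probes was 17.8% against 5.49% (gap 0.948). The area took in 44 tiles, the lowest with a median of -6.18 relative to the other arrays of the dose on the log2 scale. ZnO 16 replicate 4 had 10 low tiles, and all 596 of their spots lay within the area of ZnO 4 replicate 4. For 152 genes with a probe inside the area and another outside it, the inside probes had a median deviation of -0.50 from the other 3 arrays and the outside probes 0.0661 (quartiles -0.10 and 0.30), which argues against less of these RNAs in that sample and is what a local defect of the array surface predicts. How such a defect came to lie at the same place on both slides was not tested.

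ZnO 16 replicate 4 had 534 spots with the non-uniformity flag against a mean of 8.67 on the other arrays of the dose (gap 0.970). It also stood apart for Ccl22 (gap 0.841; -1.09 against 1.04), Nsdhl (0.947; -0.11 against -0.51) and Plin2 (0.888; 3.13 against 2.70). The Ccl22 probe lay in the low area of ZnO 4 replicate 4. Masking the areas of both arrays moved its difference only from -2.25 to -2.29, so its value on ZnO 16 replicate 4 was not among the masked spots. ZnO 16 replicate 1 stood apart for Il1b (gap 0.996; 1.68 against 0.82) and RT1-Db1 (0.888; -3.67 against -3.35), and ZnO 16 replicate 2 for Adm (0.830; -2.08 against -1.72) and Olr1 (0.901; -2.61 against -1.67). ZnO 4 replicate 2 stood apart for Dnajb9 (gap 0.864; -4.88 against -3.78) and Tlr4 (0.874; -1.33 against -0.90).

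The large number of genes that differed between the doses was weighed against 3 explanations. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many as 5614 genes, the real one. The highest of the others gave 0. Every other split mixes the slides, so a difference between slides adds to the spread within its groups and lowers its count. The count therefore cannot exclude chance in the grouping. Differences peculiar to single probes are argued against as the whole cause, since the log2 differences of the 2 brightest probes of a gene correlated across 1443 genes at 0.394, above the highest value of 0.0817 in 1000 shuffles; still, of 276 pairs with both probes called, 48 (17.4%) went opposite ways. A difference between slides, scans or the passage numbers given in the descriptions cannot be told apart from the dose, since 0 slides held both doses; the spike-in slope was 0.846 on one slide and 0.999 on the other (exact permutation p = 0.0286, adjusted 0.114). An effect of the dose stays open beside it, untested.

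Genes without a symbol were called lower more often than genes with one, and this went with the class of accession. Lower calls made up 35.4% of genes with an ENSRNOT accession and no symbol and 16.4% of those with an NM accession and a symbol, but among other accessions 24.6% without a symbol and 23.4% with one. Within bins of mean signal the odds ratio of a lower call, without against with a symbol, was 1.98 (95% interval 1.82 to 2.16), which argues against dimmer probes as the whole cause. After quantile normalization it was 2.05 (1.89 to 2.23), which argues against the scaling between arrays. Both intervals treat genes as independent and leave out variation between arrays and slides, so they are too narrow. A slide difference that depends on probe design, and a real difference in little-annotated transcripts between the doses, both stay open and were not tested.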

How the results depend on the processing

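Normexp on median signals, the masked low areas and the removal of both arrays numbered 4 were chosen after the data had been seen. The number of changed genes stayed within 1.5 times of 5614 under all other settings than a minimum fold, which left 2510 (924 higher, 1586 lower) by its construction. The direction of the calls did not: without scaling 230 genes were higher, and with spike-in scaling 227 were higher and 4653 lower, as the median of all genes moved by -0.75 and -0.76. Leaving out each array in turn gave 4309 to 5529 genes, 1953 to 2695 higher and 2293 to 2834 lower, and 7 to 10 lists called. Camera called 8 lists; with an estimated correlation 0 were called and with fry 23, which asks another question. Heat shock, ATF4 and CHOP, p53, immediate early and ribosomal protein lists were called in each of the 19 settings that kept camera at the preset correlation. The range of the list median relative to all genes was 0.45 to 0.95 for heat shock, 0.996 to 1.716 for ATF4 and CHOP, 0.30 to 0.68 for p53 targets, 1.51 to 2.25 for immediate early genes and -0.66 to -0.24 for ribosomal proteins.

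Of 118 named genes that passed the threshold, 51 kept call and direction in every setting run. Lost calls numbered 52 without scaling and 52 with spike-in scaling, where all genes shifted, 18 with normexp, besides those whose sign turned, and at most 11 in any other setting. The 18 were those of Alkbh4, Ankrd37, Casp12, Cd3d, Cdc25b, Csf3, Ctsz, Dhcr7, Egr2, Hsp90ab1, Mx1, Nars1, Nsdhl, RT1-Db1, Slc11a1, Slc30a1, Slc39a4 and Xiap, with differences of -0.73 to 0.43 relative to the shift of all genes. Their adjusted p tests the difference before that shift was taken off. Median scaling lost Egr2, Hsp90ab1, Mx1 and Slc30a1, whose differences relative to the shift stayed at -0.71, -0.44, -0.88 and 0.35. No filter on dim probes lost Casp12, Fcgr3a, Hsp90ab1, Napsa, Rps29 and Slc30a1, and no intensity trend lost Fcgr3a, Napsa, Slc30a1 and Syvn1, all with unchanged differences. Rps29 was lost with signal well above background required on all arrays (0.42, adjusted p = 0.0505). Array weights lost Syvn1 (0.66), quantile normalization Hsp90ab1 (-0.30), and the mean of probes Egr2 (-0.17), Hsp90ab1 (-0.30), Srebf1 (-0.31) and Vwf (-0.03). Masking the low areas lost Syvn1 (0.58). The removal of both arrays numbered 4 lost Hsp90ab1 (-0.41), Mt1 (-0.43), Slc30a1 (0.31) and Xiap (-0.74). The sign turned for Fcgr3a (-0.29), Napsa (-0.23), Ndrg1 (-0.00903) and Rps29 (-0.29) with normexp relative to the shift of all genes, and for Foxj1 (1.255), Rps29 (-0.35) and Xiap (0.21) with the mean of probes, whose probes disagree; for normexp the cause was not tested. Normexp with an offset of 50 shrinks differences of dim genes by construction. With the replicate number as a block 5471 genes were called, 2593 higher and 2878 lower, and the calls of Casp12 (adjusted p = 0.0655), Rps29 (0.0746) and Slc30a1 (0.0537) were lost. Arrays of the same number correlated in their deviations at -0.22 to 0.40, and 2 of 4 correlated best with their own number. This leaves open whether the numbers pair the arrays. Signal over background limits the genes not well above background at a dose to a bound. The bounds hold for the main processing only. Over the settings run, the smallest log2 differences were 3.62 for Dusp1 (bound 5.69), 3.62 for Hspa1a (5.37) and 3.34 for Gpr15lg (5.51). They were 2.54 for Fos (bound 4.42), 1.91 for Egr1 (3.16) and -2.55 for Aldh1l2 (-4.18).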

Other observations

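The gene families below were picked after the values had been seen, and camera was run on the 6 of 8 that had at least 3 measured members, with Benjamini-Hochberg adjustment over these. Because the same values picked the families, their p-values describe them and do not measure chance. Zinc finger genes named Zfp, Zbtb, Zscan, Zkscan or Znf had 50 of 122 measured members higher and 10 lower at 16 µg/mL (median 0.38, camera adjusted p = 0.000198, or adjusted p = 0.0514 with an estimated correlation). Zbtb21 rose by 3.58 (3.13 with the low area masked) and Zfp394 by 2.76, Zfp142 was at least 6.13-fold higher, and Zfp217 was at least 1.38-fold lower. Klf transcription factors had 6 of 9 higher and 0 lower (median 0.81, camera adjusted p = 0.00914, or adjusted p = 0.0514 with an estimated correlation), led by Klf6 (1.99), Klf9 (1.79) and Klf3, whose 2 probes gave 1.71 and -0.18. Dual specificity phosphatases, which act on MAP kinases among other substrates, had 5 of 11 higher and 0 lower (median 0.32, camera adjusted p = 0.0202, or adjusted p = 0.0616 with an estimated correlation). Dusp2 rose by 3.12 and Dusp5 by 2.36 beside Dusp1.

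Genes named as copies of ribosomal protein genes had 8 of 11 lower and 0 higher (median -1.60, camera adjusted p = 0.000144, or adjusted p = 0.0514 with an estimated correlation). Rps19l3 fell by 3.66, Rpl27al1 by 3.53 and Rpl17l5 by 3.10, each with all 4 values at 16 µg/mL under the 4 at 4 µg/mL. Their sequences resemble those of the parent genes, so which transcripts these probes measured is uncertain, and Rpl37l1 (-0.58) also counts in the ribosomal protein list. Id1 and Id2 were both called lower, Id1 by -3.42 with signals raised to the lowest well-above-background signal of each array and Id2 by -0.55. CCT chaperonin subunits had 2 of 7 higher (camera adjusted p = 0.184, or 0.392 with an estimated correlation), histones had 2 of 10 lower (camera adjusted p = 0.385, or 0.716 with an estimated correlation), and Snhg4, the 1 measured small nucleolar RNA host gene, differed by 0.55. Family medians relative to all genes kept their sign with quantile normalization; scalings by 1 factor per array leave them almost unchanged by construction.

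Between 2.89% and 5.39% of the spots for ERCC control sequences were well above background on an array, and between 0.325% and 1.95% of the negative control spots.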
